A study of Mus musculus and Bos taurus with 2 samples.

How the data were processed

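The study pooled about 200 in vitro produced embryos per library, from superovulated mice of the Slc:ICR stock and from oocytes of Japanese Black or Japanese Black by Holstein cattle. Per the labels' protocols, polyadenylated RNA was turned into cDNA, amplified by PCR with 14 cycles and read on a nanopore sequencer, with each library on its own flow cell. PCR copies were not marked with molecular identifiers in the protocol given. The labels put both libraries in batch 1.

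Per the file headers and attributes, the authors deposited 1 set of StringTie transcript models per library, with exon positions, a gene name, the closest reference transcript, a class code for the relation to it, a locus and a start group. The deposited files hold no read count, coverage or abundance and no score, so read depth and its effect on each model are unknown. The genome builds are mm10 for mouse and bosTau9 for bovine, per the submitters' processing notes. The aligner, read filters, tool versions and parameters are not given in the sources used here. Model identifiers carry 28 batch names in mouse and 40 in bovine. In mouse, 68.4% of the exact multi-exon matches (67.7% to 69.1%) had an intron chain identical to one in GENCODE release M21 on the same build, which was checked before mouse coordinates and that annotation were used together. Of these, 10.5% ended at both annotated ends to the base, so the ends of exact matches may in part be taken over from the reference. A filter or merging step in the assembly would lower the number of models of rare transcripts. Truncated cDNA would move starts downstream, in many cases within annotated exons. Where truncation falls inside an internal exon that the annotation lacks, that exon would count as an unannotated first exon.

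Groups came from the labels: 1 mouse and 1 bovine library. With 1 library per species, no replicate check, p-value or comparison within batches was possible. Shares of models carry exact Clopper-Pearson 95% intervals (scipy 1.17.1), which treat models as independent draws. A model was called sense for a gene when its class code was =, c, k, m, n, j or o, and the number of sense models per gene stood in for the planned abundance. Bovine results use the names and structures in the bovine models alone, since no bovine genome or annotation was used here. Gene lists were fixed before the data were examined: genes of the mouse 2-cell burst, Obox genes, genes known from activation in other mammals (bovine), maternal oocyte genes, pluripotency and lineage genes, silencing of transposable elements and DNA methylation, genes with described repeat promoters, ribosome biogenesis, splicing, transcription, chaperones, cell cycle, ribosomal proteins, oxidative phosphorylation, and markers of cumulus and granulosa cells, sperm, and blood and immune cells. Symbols were matched without regard to case, and missing mouse symbols through the synonyms of the reference table. In the cell cycle list Geminin is another name of Gmnn, and in the 2-cell list Dux is another name of Duxf3. The mean models per found gene of a list was set as a percentile among 10000 random lists of the same size drawn from genes with a model. The random lists were not matched on exon number, gene length or gene type, so a percentile can reflect gene structure. The plan named the median, but most medians of such small counts are tied, so the mean was used. List percentiles between the species were planned on abundance and were not made.

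First and last exons were called unannotated when they overlapped no exon of GENCODE M21 and no exact match of the library on the same strand, in a model of at least 2 exons that shares a splice site with an annotated gene. For bovine, and for mouse beside it, the library's exact matches alone served as the annotation. This count replaces the planned count of starts in repeats, because no genome sequence or repeat annotation of either build was used here. For the same reason the planned shares of starts in repeats, their comparison with shifted positions and every alternative built on repeats or abundance were not run. First-exon lengths were counted once per donor site from 60 to 250 bp, and each count was set against the mean of the lengths within 10 bp. Recurrent families were sought in mouse with blastn 2.17.0 (e-value 1e-05, same strand, at least 80% identity over at least 60% of the shorter exon and 50 bp, single linkage). Sequences came from annotated transcripts rather than from a genome, which departs from the plan and limits the search to first exons inside annotated exons of either strand. Linkage chains matches, so members were also counted by direct match to the member with most matches. First exons closer than 10 kb counted as 1 locus.

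Named genes were chosen by a rule fixed before the data were examined: the 15 genes with most models per library, the 15 with most models with an unannotated first exon (in place of chimeric transcripts), every found member of the activation, Obox and repeat-promoter lists, the 4 members with most models of every other list, pluripotency members without a model, the 15 same-symbol genes with the largest log2 ratio each way (pseudocount 1) among those with at least 10 models in one library, and 30 genes shared between the libraries. Ties went by symbol, and a few genes that met the rule are not named. The planned naming by abundance could not be made. The 115-bp first exons, the length scan, the Pck2 example and further members named for their first exons were chosen after their values were seen.

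Calls of unannotated first exons, first-exon families, list percentiles and matched draws were tested on simulated data. Of 200 mouse models given a first exon outside all annotation, 198 were called, and 0 of 200 with a shortened first exon were. These outcomes follow largely from the rule itself, so they check the code alone. Error sources such as truncated or misaligned reads were not simulated. All 40 planted copies of a mutated sequence fell in 1 family, with 0 other exons in it. Random gene lists had a mean percentile of 47.1, and 6.5% of them lay above the 95th percentile. Of 200 simulations without a link between the species, 1 passed the upper bound of the matched draws of shared genes, and 200 of 200 with a planted link did. These simulations set each gene's chance by the number of sense models on which the draws match. They therefore check the code, and leave out chances that depend on models that are not exact. Alternatives were models of at least 2 exons, assembled chromosomes, starts within or beyond 100 bp of annotated starts, protein-coding genes, stricter families, missing genes at 0, a pseudocount of 0.1, ranks, and those added after seeing the data. Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9 were used.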

Results

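The data were transcript models assembled from nanopore long-read cDNA of embryos at the time their own genome becomes active. One library came from mouse embryos at the late 2-cell stage, collected 36 h after in vitro fertilization, and the other from bovine embryos at the 8-cell to 16-cell stage, collected 72 h after insemination. Each library pooled about 200 in vitro produced embryos, and each species had 1 library, so no value has a replicate error and no test between the species was possible. Species, stage, hours after insemination and reference annotation differed together. The mouse library held 42028 transcript models with 292540 exons, and the bovine library 40819 models with 293209 exons. The deposited models carry no read counts, so the depth behind each model is unknown, and a gene without a model was not assembled rather than shown to be silent. Shares are given with exact Clopper-Pearson 95% intervals, which cover counting error only.

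The first comparison asked how much of each transcriptome matched known genes. Named reference genes with at least 1 model on their own strand numbered 14090 in mouse and 13375 in bovine, and in mouse these included 11723 of 21900 protein-coding genes in the reference table (53.5%, 95% interval 52.9% to 54.2%). Models with the exact intron chain of a reference transcript made up 41.4% of the mouse library (40.9% to 41.8%) and 35.7% of the bovine library (35.3% to 36.2%). Models that shared a splice junction with a reference gene but differed in structure made up 25.01% in mouse (24.6% to 25.4%) and 35.6% in bovine (35.1% to 36.1%). Models between genes numbered 5601 in mouse, 13.3% of the library (13.0% to 13.7%), and 4846 in bovine, 11.9% (11.6% to 12.2%). Among models of at least 2 exons the order turned, with 9.23% in mouse (8.94% to 9.54%) and 11.2% in bovine (10.9% to 11.5%). Inside introns lay 2858 mouse models and 1214 bovine models, and 1829 and 1322 models overlapped an exon of a gene on the opposite strand.

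Unspliced models were more frequent in the mouse library. Single-exon models made up 13.2% of the mouse models (12.9% to 13.5%) and 4.14% of the bovine models (3.95% to 4.34%). Of these, 1855 in mouse and 245 in bovine lay inside introns, and 2232 in mouse and 466 in bovine lay between genes. The intervals of these shares did not overlap, but the difference is between 2 libraries and 2 annotations. Median spliced length was 1648 bp in mouse and 1667 bp in bovine, with a median of 5 exons in both. The exact-match share rose to 56.5% in mouse and 49.3% in bovine when a start within 100 bp of an annotated start also counted as known.

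**Figure D1:**
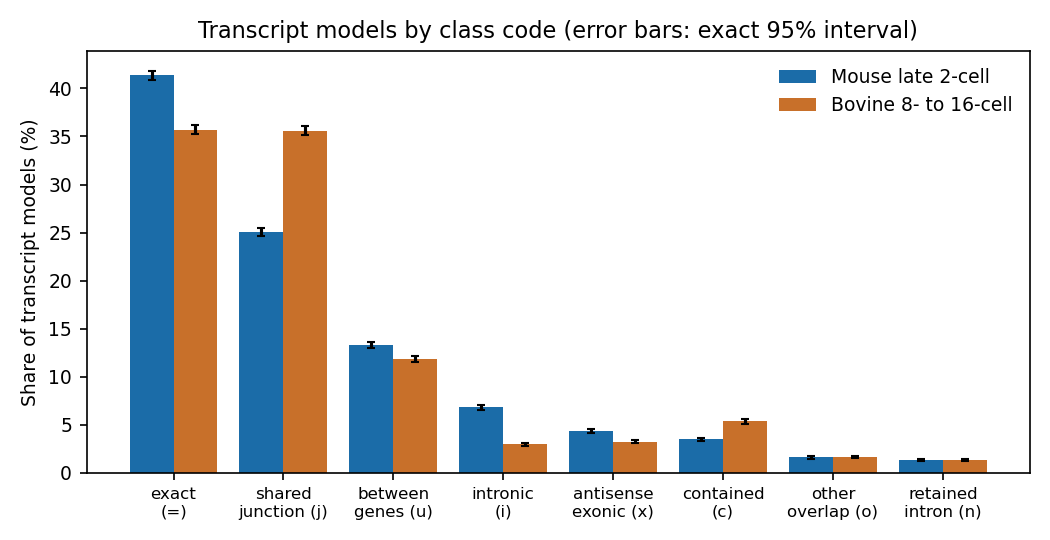
Share of transcript models (%) in each library by class code, the 8 codes most frequent in mouse, with exact 95% intervals as error bars. Exact matches stand at 41.4% in mouse and 35.7% in bovine, shared-junction models at 25.01% and 35.6%, and intronic models at 6.80% and 2.97%.

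The mouse library was searched for genes known for their brief burst of expression in 2-cell embryos. Of 31 such symbols, 25 had a model on their own strand. They included the zinc finger genes Zscan4a, Zscan4c and Zscan4d with 2, 1 and 3 models, Zfp352 with 1, and Ubtfl1 with 3. The Tdpoz genes, which encode TRAF and BTB domain proteins, gave 3 models for Tdpoz1, 3 for Tdpoz3, 1 for Tdpoz4 and 2 for Tdpoz5. The deubiquitinase genes Usp17la, Usp17lc, Usp17ld and Usp17le had 1 model each and Usp17lb had 2, while Tcstv1, Tcstv3, Gm21761 and Arg2 had 1 each. Gm20767 had 4 models, Gm8300 had 3, Gm5662, Gm2016 and Gm2022 had 2 each, Sp110 had 6, and Pramef25, listed under its newer symbol Pramel16, had 3. No sense model was found for Zscan4b, Zscan4e, Zscan4f, Tdpoz2, or for Dux under either that name or Duxf3, the symbol used in the annotation, so that 1 gene fills 2 of the 31 symbols. Dux activates many of the listed genes, and its absence concerns assembled models at 36 h only. Members of these families are near-identical copies, so the copy to which a model is assigned is uncertain. The list had a mean of 2.04 models per found gene, at percentile 34.5 of 10000 random lists of the same size.

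Among the oocyte-specific homeobox genes of the Obox cluster on chromosome 7, 6 of 8 had named models: Obox1 with 5, Obox5 with 3, Obox2, Obox3 and Obox6 with 2 each, and Obox7 with 1. The other members, Obox4-ps35 and Obox8, had no model under their names, but unnamed models, 2 and 3 respectively, overlapped their annotated exons on the same strand. Maternal oocyte genes were also well represented in mouse, with models for 31 of 34 symbols. The members with most models were Tle6 of the subcortical maternal complex with 8, Zar1l with 7, Oog1 with 6 and the translational regulator Cpeb1 with 5. Models of the zona pellucida genes were still present, 5 of them for Zp3.

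In the bovine library, 11 of 20 symbols known from genome activation in other mammals had models. CCNA1, a germ-cell cyclin, had 9, ZSCAN4 had 7, the Krüppel-like factor KLF17 had 5 and ZSCAN5B had 4. The homeobox genes DUXA and ARGFX had 2 each and DPRX had 1, KLF4 and KLF5 had 2 each, and ZNF280A and SP5 had 1 each. Symbols without a model were LEUTX, TPRX1, TPRX2, TPRX3, KDM4E, TRIM43, RFPL4B, MBD3L2 and PRAMEF12, and no other names were searched. The mean of 3.27 models per found gene stood at percentile 89.8 of 10000 random lists of the same size. Maternal genes had models for 25 of 34 symbols, led by CPEB1 with 9, NLRP2 and ZAR1 with 6 each, and NLRP5 with 5. The symbols Oog1, Omt2a, Omt2b and E330034G19Rik in that list are mouse names.

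The lineage and pluripotency genes differed in which members were assembled. Bovine had models for 22 of 26 and mouse for 19 of 26. Models of SOX2, NANOG, GATA2, GATA3 and TFAP2A, transcription factors of the inner cell mass and trophectoderm, were found in bovine with 2, 3, 2, 3 and 1 models, and none in mouse. Lin28b with 3 models and Tfcp2l1 with 1 were found in mouse alone, and CDX2 and SOX17 in neither. The members with most models were Tead4 with 6, Esrrb and Sall4 with 4 each and Lin28b with 3 in mouse, and NR5A2 with 6, KLF17 and TFAP2C with 5 each and SALL4 with 4 in bovine. With exact matches alone, an alternative chosen after seeing the data, 11 of the bovine members and 13 of the mouse members had a model.

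Genes that silence transposable elements or methylate DNA had models for 35 of 40 symbols in each library. In mouse they had a mean of 3.86 models per found gene, at percentile 99.99 of 10000 random lists of the same size, led by the histone methyltransferase gene Ehmt1 with 17, Pphln1 with 11, Cbx1 with 8 and Dnmt3l with 7. In bovine the mean was 3.06 at percentile 94.2, led by ATF7IP with 7 and by CBX5, DNMT1 and MPHOSPH8 with 6 each. These percentiles do not allow for exon number, gene length or gene type. DNMT3L, a cofactor of the de novo DNA methyltransferases, had 7 models in mouse and none in bovine, while PIWIL1 had 1 model in bovine and none in mouse. PIWIL3 had 1 model in bovine and is not in the mouse reference table.

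Housekeeping lists were nearly complete in both libraries. Ribosome biogenesis and splicing had models for 50 of 50 symbols in each. Ribosome biogenesis was led by Ubtf with 8, Nop56 and Wdr12 with 7 each and Gar1 with 5 in mouse, and by NPM1 with 6 and GAR1, UBTF and UTP20 with 5 each in bovine. Splicing was led by Srsf7 with 10, Sf1 with 8, Srsf11 with 7 and Lsm7 with 6 in mouse, and by SF1 with 10, SF3B1 and SRSF5 with 8 each and SRSF10 with 7 in bovine. Its mean models per gene stood at percentile 99.2 in mouse and 95.5 in bovine. The transcription machinery had models for 44 of 45 symbols in mouse, led by Taf6 with 7, Ccnt1 and Med1 with 6 each and Ccnt2 with 5, and for 41 of 45 in bovine, among them TAF12 with 6, and MED1 and TAF2 with 5 each. The symbols without a bovine model, Supt4a, Supt5, Supt6 and Supt16, are mouse names. Chaperones had models for 24 of 24 and 23 of 24 symbols, with 1.75 and 1.39 models per gene at percentiles 8.94 and 0.03. Their leading members were Hspa4 with 4 and Cct6a, Hspa8 and Hspd1 with 3 each in mouse, and CCT4, CCT7, DNAJB1 and HSP90AB1 with 2 each in bovine. Cell cycle genes had models for 37 of 41 symbols in each, led by Cdk2 with 7, Cdc25c with 5, and Aurkc and Bub1 with 4 each in mouse, and by AURKB with 7, CDC25B and PLK4 with 6 each and BUB1 with 5 in bovine. Ribosomal protein genes with models numbered 88 in mouse, at percentile 96.5, and 81 in bovine, at percentile 8.06, led by Rps18 with 9 and Rpl17, Rpl36 and Rps19 with 6 each, and by RPL35A with 7, RPL28 and RPL36 with 5 each and RPL12 with 4. Oxidative phosphorylation genes numbered 89 and 83, at percentiles 1.49 and 0.285, led by Atp5j and Ndufs1 with 7 each, Ndufa9 with 6 and Cox6b2 with 5 in mouse, and by ATP5PF with 6, ATP5MC1 and SDHD with 5 each and ATP5MD with 4 in bovine.

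Markers of other cells that an embryo pool can carry were less complete. Cumulus and granulosa markers had models for 14 of 23 symbols in mouse, led by Fn1 with 4, Hsd3b1 with 3, and Lhcgr and Tnfaip6 with 2 each, and for 13 of 23 in bovine, led by HAS2, TNFAIP6 and VCAN with 3 each and COL1A1 with 2. Sperm markers had models for 4 of 16 in mouse (Odf2, Ldhc, Prm2 and Tnp1, with 17, 5, 1 and 1) and for 6 of 16 in bovine, led by ODF2 with 20, LDHC with 8, and ODF1 and SPATA18 with 1 each. Blood and immune markers had models for 4 of 15 in mouse (Cd74 and Cd79a with 2 each, C1qa and Lyz2 with 1 each) and for 5 of 15 in bovine (CD3E, HBA, HBA1, HBB and PTPRC with 1 each). The globin symbols Hba-a1, Hba-a2, Hbb-bs and Hbb-bt in that list are mouse names, while HBA, HBA1 and HBB are not. By mean models per found gene, the sperm list stood at percentile 99.4 in mouse and 99.3 in bovine. These percentiles rest largely on Odf2, with 17 of the list's 24 models in mouse and 20 of 32 in bovine. The median number of models per found gene of the sperm list was 3 in mouse and 1 in bovine. The cumulus and granulosa list stood at 4.6 and 3.6, and the blood and immune list at 23.0 and 0.7.

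**Figure D2:**
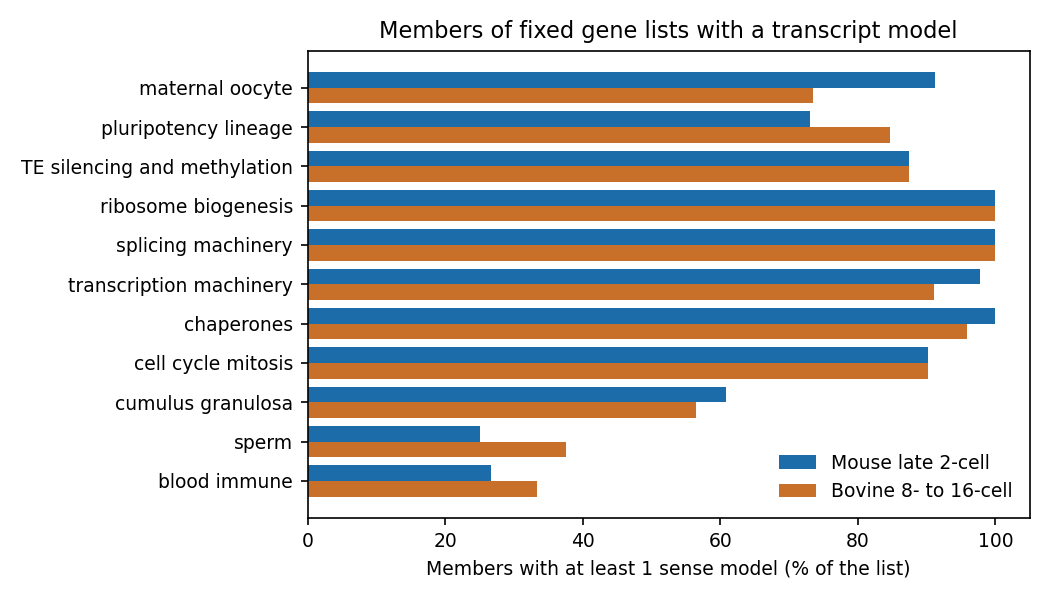
Percent of the symbols of each fixed gene list that have at least 1 model on the gene's own strand, mouse and bovine side by side. Ribosome biogenesis and splicing reach 50 of 50 symbols in both libraries, while pluripotency and lineage genes stand at 19 of 26 in mouse and 22 of 26 in bovine.

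The series concerns chimeric transcripts in which a transposable element supplies part of a gene's transcript. Repeats were not assigned here, so the comparison counted multi-exon models that share a splice site with an annotated gene and whose first exon overlaps no annotated exon. In mouse, 3737 of 13035 gene-linked models that were not exact matches had such a first exon (28.7%, 27.9% to 29.5%), and 1291 had such a last exon (9.90%, 9.40% to 10.4%). The 3737 models belonged to 2364 genes and used 2832 distinct first-exon donor sites. Of them, 1418 started upstream of the gene's outermost annotated start, at a median distance of 6.50 kb. Annotated protein-coding genes accounted for 3115 of the models and 1974 of the genes.

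The mouse protein-coding genes with most such models were Slc22a28, an organic anion transporter family gene at chromosome 19: 8062209 to 8131982 (mm10), with 10 models from 1 donor, Plcd4 with 9 and Atp6ap1l with 8. They were followed by 1700069L16Rik, Fam98b, Fbxo47, Rimklb and the kinase gene Stk11 with 7 each, and by Ccdc63, Chn1, Dlgap2, Dtnb, Hipk3, Phrf1 and Pigq with 6 each. Models of Fam98b began up to 3.70 kb upstream of the annotated gene, those of Stk11 up to 2.36 kb, those of Atp6ap1l up to 9.22 kb and those of Hipk3 up to 20.8 kb. No such model of Slc22a28, Plcd4 or Fbxo47 began upstream of the gene. Genes of the 2-cell list also had such models, 2 each for Gm20767, Pramef25 and Zscan4a and 1 each for Gm8300, Sp110, Ubtfl1 and Zscan4d. The lineage gene Tead4 had 6 such models, and among the genes that act on DNA methylation and chromatin, Dnmt3l and Ehmt2 had 3 each and Trim28, Uhrf1 and Dnmt3a had 2 each.

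A rule that both libraries allow, in which the exact matches of the same library served as the annotation, gave 2405 mouse models of 1477 genes and 2378 bovine models of 1383 genes. This rule was chosen after seeing the data. The share among gene-linked models was 33.7% in mouse (32.6% to 34.8%) and 26.2% in bovine (25.3% to 27.1%). Of the bovine models, 1121 started upstream of the gene's exact matches, at a median distance of 1.05 kb, and of the mouse models 1058 did by the same rule, at a median of 4.75 kb. Last exons without annotation made up 13.4% in mouse (12.6% to 14.2%) and 19.7% in bovine (18.9% to 20.6%). First exons thus outnumbered last exons by 2.52 to 1 in mouse and 1.33 to 1 in bovine. By either rule a longer exon is more likely to touch an annotated exon, and exon length was not allowed for. The rule counts reference isoforms that were not assembled as unannotated: of the 2405 mouse models, 74.7% (72.9% to 76.4%) were also without annotation in GENCODE, and no such check was made for bovine.

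Bovine genes with many such models included ELAVL2, an RNA-binding protein gene at chromosome 8: 20308269 to 20444922 (bosTau9, span of its exact matches), with 11, and the chromatin reader gene ZMYND8 with 10. SHISA5 had 9, CTBP2, RAB4B and TDRD5 had 8 each, DTNB, DYNC1I1, STX8 and ZCCHC6 had 7 each, and ARL6IP6, FBXO21, KMT5B and LOC100847951 had 6 each. All 11 models of ELAVL2 began upstream of its exact matches, up to 4.95 kb away, and all 8 of the germline gene TDRD5 up to 4.55 kb away. Among the fixed lists, NR5A2 and AGO2 had 4 such models each, ZSCAN5B, TET1, TET3, NLRP14 and RPL35A had 3 each, POU5F1 and SOX15 were among those with 2, and DUXA had 1.

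Of 5638 same-symbol genes with an exact multi-exon match in both libraries, 931 had such a first exon in mouse, 892 in bovine and 198 in both. Shared genes with a high smaller count included DTNB (6 mouse and 7 bovine models), ZMYND8 (4 and 10), PTP4A2 (4 and 4), ELAVL2 (3 and 11), RIMKLB (7 and 3), CDK8 (5 and 3), BORCS7 (4 and 3), SMARCA2 (3 and 4), GATAD2A, MEPCE and RTN4 (3 and 3 each), TLK2 (6 and 2), TLK1 (2 and 5), CTPS2, MLLT3, RDH10, TIAL1, BABAM2, MPHOSPH9, PARN, RNF8, THAP4, UBE2H, WDR34, ARMH3, ATF1, CTNND1, DHODH and NSMCE4A.

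Cdk2ap1 and Dicer1, known from earlier work for promoters in transposable elements in preimplantation embryos and rodent oocytes, were looked up by structure. Mouse Cdk2ap1, a regulator of the kinase CDK2, had 1 model, on the minus strand of chromosome 5, with 4 exons and no exact match. Its first exon (124362950 to 124363847, 898 bp) began 765 bp upstream of the outermost annotated start, overlapped an annotated exon and was spliced to the exon at 124350078 to 124350172. Mouse Dicer1, on chromosome 12, had 2 models with 28 and 6 exons that both started at 104752892, 940 bp upstream of the outermost annotated start, in a first exon without annotation. Bovine CDK2AP1 had 3 models starting at 52306876, 52307604 and 52307880 on chromosome 17, and bovine DICER1 had 3 models on chromosome 21, none of them an exact match. Whether any of these mouse or bovine starts lies in a transposable element, or is a promoter described earlier, was not tested.

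The lengths of first exons showed one value that recurred across the mouse genome. Among 2479 distinct first-exon donors of multi-exon models between genes, 130 closed a first exon of exactly 115 bp (5.24%, 4.40% to 6.20%), 5.80 times the mean of 22.4 for the lengths within 10 bp. The 130 donors lay at 130 separate loci on 20 chromosomes. Lengths of 121, 109 and 108 bp followed with 50, 47 and 44 donors. In bovine the same length had 7 of 3209 donors (0.218%, 0.0877% to 0.449%), and the commonest length, 157 bp, had 20. Among the 2832 donors of unannotated first exons spliced to mouse genes, 115 bp was again the commonest length with 67 (2.37%, 1.84% to 2.99%), while the commonest length among exact matches, 139 bp, had 59 of 11070 donors, 1.33 times the mean of the lengths around it.

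**Figure D3:**
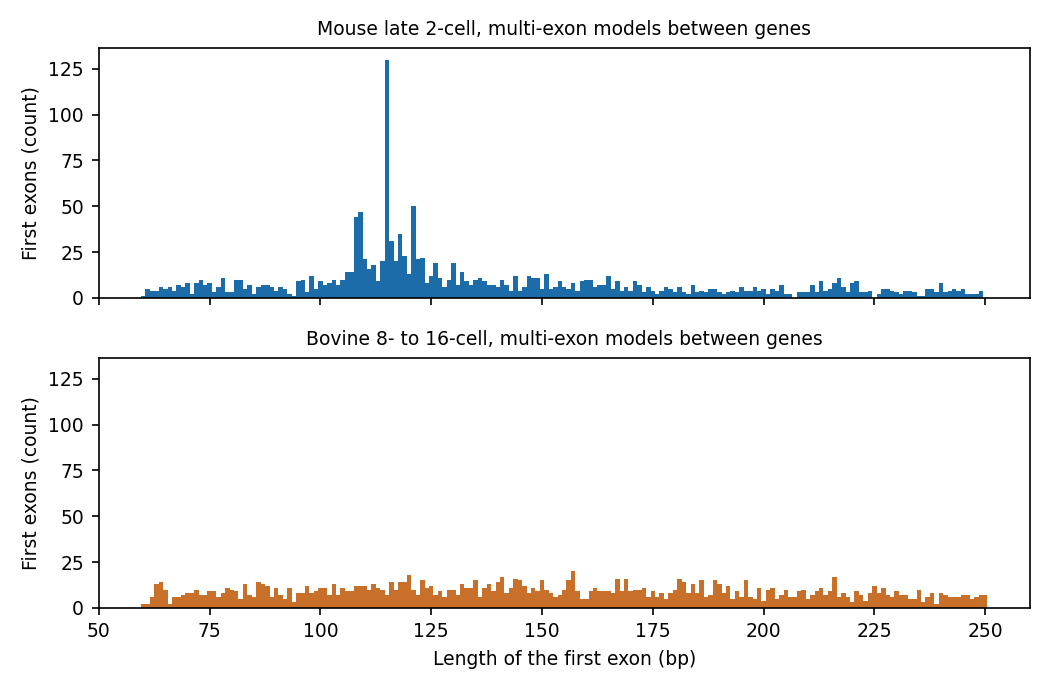
Number of distinct first exons of multi-exon models between genes (y) by length in bp (x), mouse above and bovine below on the same scale. The mouse library has 130 first exons of 115 bp, while the bovine count stays at 20 or below at each length.

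First exons were then compared with each other by sequence in mouse, for the 12545 of 26919 distinct first exons (46.6%) that lie inside an annotated exon of either strand and so have a known sequence. Of these, 11862 were at least 50 bp long and were compared. The largest group formed by chaining matches held 91 first exons at 77 loci on 20 chromosomes, but only 1887 of its 4095 pairs matched directly, so it holds more than 1 sequence. Around the member with most direct matches, a restriction chosen after seeing the data, stood 64 first exons at 55 loci on 19 chromosomes, 13 of them of 115 bp, and the other 27 joined through chains alone. Restricted to first exons of 100 to 130 bp, also chosen after seeing the data, the largest group held 41 loci. Of the 64 direct matches, 45 shared a splice site with an annotated gene, 25 of them with a protein-coding gene. They included the 2-cell gene Gm20767, Naalad2, Fbxo15, Ccpg1, Nme6 and Pck2, while Ubtfl1, Utp14a, Xiap and Cd59b were joined by chaining. Known sequence covered 69.2% of the first exons of exact matches but 2.52% of those between genes, so the group's size in the library was not measured. By the same chaining, the largest group among second exons held 78 loci on 15 chromosomes and that among last exons 348 loci on 20. These groups differ in exon length, so their sizes are not like for like. Of the 80 second exons, 76 had 127 bp. The median was 1386 bp for the last exons and 118 bp for the 91 first exons.

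Pck2, which encodes the mitochondrial phosphoenolpyruvate carboxykinase, is 1 of 54 protein-coding genes with an unannotated first exon of 115 bp, 25 of which start upstream of the gene. It was singled out after its values were seen because the sequence of its first exon is known, from an annotated exon on the opposite strand. One model matched the reference and started at 55540395 on the plus strand of chromosome 14. The other started 7.53 kb upstream of the outermost annotated start, in a first exon at 55532737 to 55532851 that was spliced to the annotated exon at 55542406 to 55542651. It had 9 exons against 10 in the exact match, whose exon at 55543589 to 55543773 it lacked. The sequence of that first exon is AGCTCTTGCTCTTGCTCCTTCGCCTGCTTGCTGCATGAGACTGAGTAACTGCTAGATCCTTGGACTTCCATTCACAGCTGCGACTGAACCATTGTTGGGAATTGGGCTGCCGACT.

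**Figure D4:**
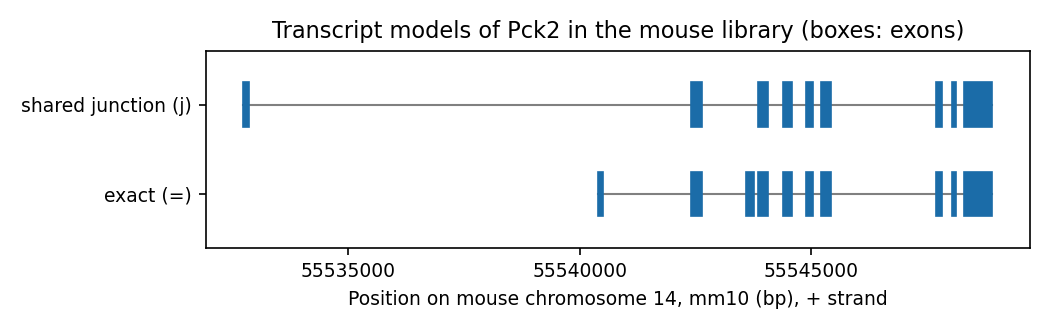
Exons (boxes) and introns (lines) of the mouse models of Pck2 along chromosome 14 (mm10, x in bp). The shared-junction model begins at 55532737, upstream of the exact match that begins at 55540395, shares the exon starting at 55542406, and lacks the exact match's exon at 55543589 to 55543773.

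The last comparison set the number of models per gene side by side for 8466 genes with the same symbol in both libraries, 60.1% of the mouse and 63.3% of the bovine genes. Mouse genes with most models were Pcbp2 with 36, Fubp1 with 31, Bag6 with 24, Cuedc2 and Trip12 with 21 each, Pum2, Sun1 and Supt20 with 20 each, Ktn1, Sp140 and Tjap1 with 19 each, Hnrnpc, Rsrc2 and Sfi1 with 18 each and Acbd5 with 17. Bovine genes with most were PCBP2 with 26, UBAP2L and ZC3H11A with 22 each, STRADA with 21, ODF2, YTHDF3 and ZMYND8 with 20 each, PUM2 with 19, SSX2IP with 18, HNRNPA2B1 and SUPT20H with 17 each, HNRNPK, KIAA1551 and PHF20 with 16 each and ADAT1 with 15. In 19 genes both libraries had at least 10 models, against 1.51 for independent lists, among them PCBP2, PUM2, ODF2, UBAP2L, HNRNPA2B1, CNOT2, RBM10, ELAVL2, HNRNPH3, HNRNPH1 and RBM39.

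The mean was 2.23 models per gene in mouse and 2.48 in bovine, and 26.5% of mouse genes (25.7% to 27.2%) and 33.9% of bovine genes (33.1% to 34.7%) had at least 2 separate start groups. Spearman's correlation of models per gene was 0.251 across the shared genes, which are not independent replicates. It was 0.0392 when genes of either library entered, with missing genes at 0. More models were found in bovine for 3366 genes, in mouse for 2765 and equal numbers for 2335. Ranks within each library gave 3367, 5098 and 1, since the genes with equal numbers nearly all counted toward mouse. Among genes with at least 10 models in one library, the largest log2 ratio of models plus 1 toward mouse was 3.32 for Tjap1 (19 against 1), followed by the histone methyltransferase gene Ehmt1 at 3.17 (17 against 1). The others were Epn2, Cwc22, the Polycomb gene Ezh2 (12 against 1), Tnip1, Sfi1, Nt5c3b, Phf7, Tfdp1, Nubp2, Plcd4, Slc39a11, Sun1 and Bag6. Toward bovine, IMMP1L and LRCH3 stood at -2.91 (1 against 14 in each), followed by ATXN7L1, SLC35A5, CHD1L, HMBOX1, MBNL3, STX8, SSX2IP, ACER3, AMZ2, APLP1, ATXN1, PSRC1 and RAB4B.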

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

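The test of wrong strands, the test of random joining and the bovine share of intronic models were chosen after the result was seen. Multi-exon models that match an intron of a reference gene but lie on its opposite strand were outside the comparisons, and they stand here because they occurred at all: 42 in mouse and 89 in bovine. A candidate technical explanation is that reads were given the wrong strand. Of these 131 models, 31 shared an intron to the base with a transcript of the other strand (23.7%, 16.7% to 31.9%) and 112 within 10 bp (85.5%, 78.3% to 91.0%). Such a match is how the class is defined, so wrong strands cannot be told apart for these models, and no biological explanation was tested.

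Possible sources of the recurrent first exons in the mouse library (77 loci with chaining) include copies of a duplicated gene. Random joining of an abundant RNA to other cDNA during PCR is another. Random joining would place the second exon at arbitrary bases, but most members have an annotated first exon or share the acceptor itself with the gene, which fixes the outcome. Outside these, 3 of 3 members had an annotated acceptor (100%, 29.2% to 100%), too few to decide, so random joining cannot be told apart. Neither can duplicated genes for part of the members: 20.8% of 48 with a known second exon (10.5% to 35.0%) matched the second exon of another member, between the bounds of 50% and 10% set for the test. No biological explanation was tested, and repeats were not assigned here.

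Single-exon models numbered 5542 in mouse against 1689 in bovine, and those inside introns 1855 against 245. Unspliced precursor RNA would put most intronic models on the strand of the surrounding gene. Only 36.8% of 1539 mouse models inside protein-coding genes lay on that strand (34.4% to 39.2%). If the strands of the models are right, this argues against precursor RNA as the source of most of the mouse set. Precursor RNA read without strand would fall on both strands, so it stays open. Inside genes with exact matches the share was 36.6% of 699 in mouse (33.0% to 40.3%) and 61.8% of 76 in bovine (49.98% to 72.8%). Genomic DNA or reads without strand would give about equal numbers on both strands, and the same 36.8% lies below the range of 40% to 60% set for that case but above the bound of 25% that would exclude it, so a part from such sources cannot be told apart. Species and stage remain open as biological explanations and were not tested.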

How the results depend on the processing

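With 1 library per species, no paired analysis was possible because the groups share fewer than 2 replicate numbers, and nothing could be left out. Read depth is unknown, which limits any statement about missing genes. Not run, for lack of abundances or repeat positions, were the alternatives with a TPM of at least 1, the highest transcript of a gene, and all those on starts in repeats or repeat shares of exon 1. Alternatives restricted to exact matches, to the library's own exact matches, to one donor each, to direct matches or to first exons of 100 to 130 bp were chosen after seeing the data. Exact-match shares moved to 44.9% in mouse with models of at least 2 exons, and to 56.5% in mouse and 49.3% in bovine when a start within 100 bp of an annotated start counted as known. Mouse gene-linked models with an unannotated first exon fell to 2405 with the library's exact matches alone, which by construction judges fewer genes. The loci of the leading group of first exons fell to 41 among first exons of 100 to 130 bp. With exact matches alone, the found members of the repeat-promoter list fell to 0 in mouse and 0 in bovine. By the same restriction bovine activation genes fell to 6, bovine pluripotency genes to 11 and bovine silencing genes to 21. The cause was not tested. The correlation of models per gene fell to 0.0392 with genes of either library, where missing genes at 0 enter by construction. The log2 ratio of genes with more models in bovine to genes with more in mouse turned to -0.60 with ranks within the library, by construction: the 2335 genes with equal numbers nearly all counted toward mouse, where the same number of models has a higher rank, while the bovine count went from 3366 to 3367. The other 32 alternatives for values that answer a comparison stayed within their bounds (a count within 1.5 times, a share within its interval, a mean within 10%), though the filter on a level of 1 or more removed no gene. Among single genes and list means, 46 alternatives moved and 51 stayed within bounds.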

Other observations

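The test of first-exon length below, and the rule for first exons that the test of shared genes uses, were chosen after the result was seen. Spliced models that joined neighbouring genes were rare in both libraries. In mouse, 17 models shared introns with the exact matches of 2 genes that do not overlap, over 12 gene pairs, and in bovine 18 models over 15 pairs. Mouse pairs included Uxt with Elk1, Zgpat with Lime1, Dhps with Wdr83os, Snhg4 with Matr3 and Gm4349 with Arnt, the last with 3 models. Bovine pairs included INO80B with WBP1 and NICN1 with AMT.

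Over all models, retained introns were similarly frequent in both libraries, 2.38% of mouse models (2.23% to 2.53%) and 2.27% of bovine models (2.13% to 2.42%). Among models of at least 2 exons the shares were 2.72% in mouse (2.56% to 2.90%) and 2.32% in bovine (2.17% to 2.47%). These intervals did not overlap. The longest mouse model was a single exon of 65535 bp assigned to Gm20590 at chromosome 13: 74505022 to 74570556. It was followed by 28873 bp for Gm21909 and 15607 bp for the pseudogene Vmn2r-ps106. All were single-exon exact matches, while the longest mouse model of at least 2 exons had 12801 bp. Ends of exact matches may in part come from the reference, so these lengths need not be those of RNA molecules. The longest bovine model was an unnamed 2-exon model of 15110 bp on chromosome 2, followed by ALMS1 with 23 exons and 13383 bp.

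A hypothesis was that some genes tend to gain unannotated first exons in both species. Genes with many models have more chances, so the 198 shared genes were set against 10000 draws matched on the number of models in each library. The draws ranged from 115 to 182 with a median of 146, and 0 of them reached 198. Chance overlap given the number of sense models per gene therefore does not account for the 198 genes. The matched number includes exact matches, which are never counted as having such a first exon. Models that are not exact were not matched, so more chances in both libraries stay open. Isoforms present in both annotations but not assembled, gene length and shared biology may also contribute and were not separated.

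Genes with many models in one species tended to have many in the other, which the number of exons per gene might explain. Within groups of genes with the same largest exon number in mouse, the rank correlation was 0.199, compared with 0.251 without grouping, and above the bound of 0.1 set for the test. Exon number by this measure therefore does not account for the whole correlation. The measure came from the assembled mouse models alone, so it may miss part of the effect of exon number. Depth per gene, which the data do not give, stays open.

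The 115-bp first exons may belong to the largest group of similar first exons. Of 26 first exons of that length with a known sequence, exact and contained models left out, 13 were members (50%, 29.9% to 70.1%), against 8 of 612 with 140 bp to under 200 bp (1.31%, 0.566% to 2.56%). Membership of the rest of the 115-bp first exons cannot be told apart, because most lie outside annotated exons and had no sequence here.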
